A study of Arabidopsis thaliana with 20 samples.

How the data were processed

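Gene expression was measured in whole leaves of Arabidopsis thaliana, per the labels, in 20 libraries of poly-A RNA made with a dUTP protocol. They cover Col-0 and ilp1-1 at 0, 4, 8, 16 and 30 h, with 2 libraries each. The labels do not tell whether the replicates are separate plants or pools, so p-values measure only the spread between these samples. Per the labels, plants grew in 10 h days, and high light began 2 h into the day, so light and time of day change together. No libraries kept in normal light at the later hours were analysed here.

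The authors deposited 10 tables, 1 per genotype and time, of FPKM values for 33104 genes. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and TAIR10 were used. Their options, the strand setting, the annotation version and the tool that made the FPKM values are not given in the sources used here. In each library, FPKM times gene length was a whole multiple of 1 step, within a tolerance of 0.001 reads (largest distance 7.87e-05), which gave back the reads per gene. The FPKM denominators were proportional to median-of-ratios size factors over all 20 libraries, so the 10 tables share 1 normalization. They stood at 0.889 to 1.18 times the recovered reads.

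Depth ran from 11.4 to 19.0 M recovered reads per library. Of 33104 genes, 18462 were above 0 in every library. Tests used log2(FPKM + 1) of the deposited values for the 19311 genes, 197 of them unnamed transcript models, with FPKM of at least 1 in at least 2 libraries. The pseudocount of 1 understates fold changes of genes at low levels. Means of the 10 groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend; 10 residual and a median of 5.12 prior degrees of freedom). The 18 contrasts were the genotype difference as a mean and at each of 5 times, 4 changes from 0 h in each genotype, and 4 differences between genotypes in these changes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast.

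For 25 gene lists (548 members, 542 distinct genes, since SUC2, CSD1, CSD2, ASN1, AGO1 and DCL1 are each in 2), limma's camera tested each list against all other genes. It used its preset correlation of 0.01 and, beside it, a correlation estimated from the data, with adjustment over the 25 lists. Lists, contrasts, tests, filter, most alternatives and the rule for naming genes were set before the data were examined. ILP1 comes first in every group. For the mean difference and for Col-0 at 4 h, the 8 highest and 8 lowest fold changes among genes that passed are named. For each other contrast these are the 4 highest and 4 lowest. These genes needed a mean of at least 5 FPKM in the higher group (for differences of changes, in 1 of the 4 groups). The mean difference also needed the same sign at all 5 times, and a contrast of 2 groups needed both libraries of one above both of the other. Up to 4 members of each list, by smallest adjusted p, were named, and other members may be given with their values. Genes without a symbol carry their identifier, and unnamed transcript models their position.

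Of 100 genes simulated with 2-fold and 100 with 1.5-fold changes, the mean contrast recovered 92 and 84% (11 unchanged genes called). At 4 h it was 61 and 26% (4 such calls). With only 200 of 19311 genes changed the cutoff is stricter than in the data, so these shares do not carry over. The mean contrast called the changed list and 0 of 24 others. Real, correlated lists were not tested for false calls. Alternatives set beforehand were a pseudocount of 0.1, no filter, size factors from genes above 1 FPKM in every library, no trend, the replicate block, the contrast's own libraries alone, and each library left out in turn. Added after the data were seen were scaling by total recovered reads, limma-voom on the recovered reads, and a fit without the 4 ilp1-1 libraries of 4 h and 8 h. Replicate numbers were not used to pair libraries. Intron numbers came from the reference annotation. Splicing and isoforms were not analysed here. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.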

Results

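Poly-A RNA from whole leaves was sequenced in 20 libraries of Arabidopsis thaliana. Plants 4 weeks old of the wild type Col-0 and of ilp1-1, a line mutated in the gene of the spliceosome-associated protein ILP1, were taken at 0, 4, 8 and 16 h of high light. A last harvest at 30 h followed 24 h of high light and 6 h of normal light. Each of the 10 combinations of genotype and time had 2 libraries. The reads recovered from the deposited FPKM values came to 18.4 and 16.2 M for the Col-0 libraries at 0 h, 14.4 and 13.0 M at 4 h, 14.8 and 14.4 M at 8 h, 12.5 and 14.0 M at 16 h, and 13.5 and 12.4 M at 30 h. For the libraries labelled ilp1-1 they came to 19.0 and 11.4 M at 0 h, 15.69 and 14.6 M at 4 h, 13.3 and 12.2 M at 8 h, 13.4 and 12.6 M at 16 h, and 13.6 and 12.4 M at 30 h. Values after a gene name are differences of log2(FPKM + 1) ± SE, and positions are on TAIR10. Plastid-encoded transcripts took 0.203 and 0.453% of the reads in the ilp1-1 libraries of 4 h and 0.0995 and 0.129% in those of 8 h. In the other 16 libraries that share lay between 0.0188 and 0.0349%.

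ILP1 (AT5G08550, chromosome 5, 2765642 to 2770282), the gene named by the mutant, was not lower in the libraries labelled ilp1-1. In Col-0 its level was 3.26 ± 0.88 FPKM at 0 h (SD, n = 2), 3.12 ± 0.29 at 4 h, 3.33 ± 0.23 at 8 h, 3.41 ± 0.06 at 16 h and 2.85 ± 0.27 at 30 h. In the libraries labelled ilp1-1 it was 8.03 ± 1.22 FPKM at 0 h, 4.85 ± 0.25 at 4 h, 4.99 ± 0.28 at 8 h, 3.52 ± 1.13 at 16 h and 3.18 ± 0.22 at 30 h. The genotype difference passed the test at 0 h (1.09 ± 0.18, adjusted p = 0.000381) and at 4 h (0.51 ± 0.18, adjusted p = 0.039), not at 8 h (0.47 ± 0.18, adjusted p = 0.0564), 16 h (0.013 ± 0.18, adjusted p = 0.971) or 30 h (0.12 ± 0.18, adjusted p = 0.655). The call at 0 h (adjusted p from 6.44e-06 to 0.0524 over the alternatives) ended on the 4 libraries of that hour alone. That at 4 h (0.0116 to 0.171) ended without a filter, on its 4 libraries alone, and without any 1 of these, with values from 0.44 without Col-0 4 h replicate 2 to 0.58 without Col-0 4 h replicate 1. At 8 h it passed with total-read scaling and with limma-voom (0.0271 to 0.217). FPKM over the whole gene also counts shortened transcripts, so these values do not tell how much intact ILP1 message each genotype held. Every direction below is that of the libraries as labelled.

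**Figure D1:**
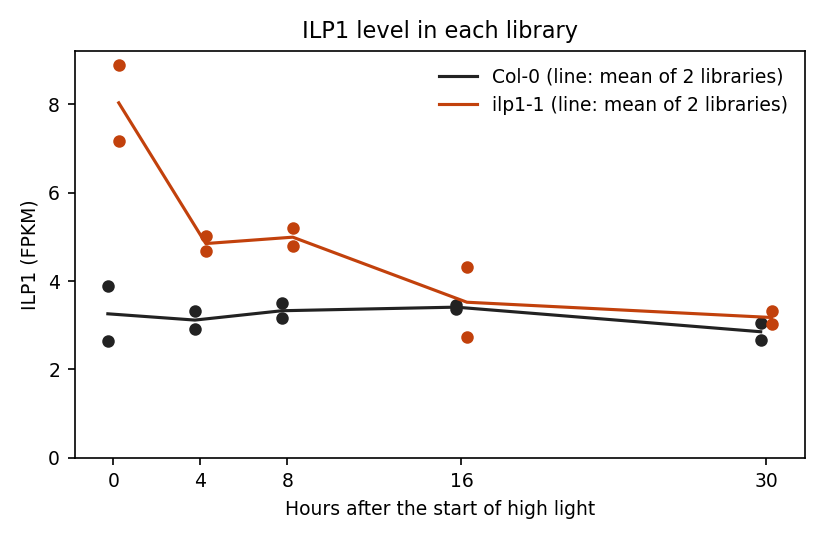
FPKM of ILP1 (linear axis) against hours after the start of high light. Points are single libraries and lines join the means of 2 libraries per genotype and time. The widest gap is at 0 h, 8.03 FPKM in the libraries labelled ilp1-1 against 3.26 in Col-0.

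The genotypes were compared by the mean difference over the 5 time points (10 libraries against 10). It need not hold at each hour: most antenna genes were higher at 8 h. Transcripts of the photosynthetic apparatus were lower in the libraries labelled ilp1-1. Of the nuclear genes for photosystems and electron transport, 0 of 26 measured were higher, 26 lower and 0 did not pass (0 and 26 adjusted over the list alone). The largest calls there were FNR2 (LFNR2, AT1G20020, -1.20 ± 0.025), PSBO2 (AT3G50820, -0.90 ± 0.02), PSAD1 (AT4G02770, -0.81 ± 0.022) and PSBO1 (AT5G66570, -0.76 ± 0.022) (camera adjusted p = 1.15e-18, adjusted p = 0.0763 with an estimated correlation). Of the Calvin-Benson cycle, which fixes carbon dioxide, 0 of 20 measured were higher, 20 lower and 0 did not pass (0 and 20 adjusted over the list alone) (camera adjusted p = 1.49e-15, adjusted p = 0.0763 with an estimated correlation). Among them were RBCS2B (RBCS-2B, AT5G38420, -1.32 ± 0.025), CP12-2 (AT3G62410, -1.17 ± 0.037) and SBPASE (AT3G55800, -0.87 ± 0.028). Of the light harvesting antenna, 0 of 17 measured were higher, 16 lower and 1 did not pass (0 and 16 adjusted over the list alone) (camera adjusted p = 5.38e-12, adjusted p = 0.0945 with an estimated correlation). They included LHCB1.3 (AT1G29930, -0.99 ± 0.022), LHCB5 (AT4G10340, -0.79 ± 0.021) and LHCA2 (AT3G61470, -0.77 ± 0.022). Of chlorophyll biosynthesis, 1 of 20 measured were higher, 16 lower and 3 did not pass (1 and 16 adjusted over the list alone) (camera adjusted p = 3.4e-08, adjusted p = 0.0763 with an estimated correlation). Genes that passed included PORB (AT4G27440, -1.64 ± 0.041), a protochlorophyllide reductase, and CHLG (AT3G51820, -1.03 ± 0.033), the chlorophyll synthase. Of photorespiration, 2 of 16 measured were higher, 14 lower and 0 did not pass (2 and 14 adjusted over the list alone) (camera adjusted p = 3.4e-08, adjusted p = 0.114 with an estimated correlation). Lower members included GDCT (AT1G11860, -0.77 ± 0.025) and GOX2 (AT3G14415, -0.54 ± 0.019). Both higher members were CAT2 (AT4G35090, 0.29 ± 0.033), the leaf peroxisomal catalase, and GLDP2 (AT2G26080, 0.17 ± 0.038), a subunit of glycine decarboxylase. The plastid-encoded read share stood up to 0.453% in the ilp1-1 libraries of 4 h and 8 h that enter this mean.

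Carbon storage and nitrogen assimilation were also lower on balance. Of starch synthesis and breakdown, 8 of 34 measured were higher, 23 lower and 3 did not pass (8 and 23 adjusted over the list alone) (camera adjusted p = 0.000622, adjusted p = 0.347 with an estimated correlation). These took in APL1 (ADG2, AT5G19220, -1.14 ± 0.039), a subunit of ADP-glucose pyrophosphorylase, and PGM (PGMP, AT5G51820, -0.76 ± 0.035), the plastid phosphoglucomutase. GBSS1 (AT1G32900, 1.32 ± 0.046), the granule-bound starch synthase, was higher. Of nitrogen uptake and assimilation, 4 of 30 measured were higher, 17 lower and 9 did not pass (4 and 19 adjusted over the list alone) (camera adjusted p = 0.000446, adjusted p = 0.0945 with an estimated correlation). The nitrite reductase NIR1 (AT2G15620, -1.07 ± 0.047) and the plastid glutamine synthetase GS2 (GLN2, AT5G35630, -0.79 ± 0.032) were lower, and so was LBD37 (AT5G67420, -1.16 ± 0.044), a repressor of nitrogen-responsive genes.

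Several groups were higher in the libraries labelled ilp1-1. Of anthocyanin and flavonoid genes, 23 of 25 measured were higher, 1 lower and 1 did not pass (23 and 1 adjusted over the list alone) (camera adjusted p = 4.47e-11, adjusted p = 0.115 with an estimated correlation). Some of these were the transcription factor PAP2 (MYB90, AT1G66390, 2.12 ± 0.15), TT7 (CYP75B1, AT5G07990, 1.32 ± 0.11), FLS1 (AT5G08640, 1.16 ± 0.046) and the chalcone synthase TT4 (CHS, AT5G13930, 1.08 ± 0.043). The lower member was MYBL2 (ATMYBL2, AT1G71030, -0.54 ± 0.067), a repressor of the pathway. Of salicylic acid and immunity, 20 of 25 measured were higher, 1 lower and 4 did not pass (20 and 1 adjusted over the list alone) (camera adjusted p = 8.48e-06, adjusted p = 0.366 with an estimated correlation). Among them were WRKY46 (AT2G46400, 1.31 ± 0.093), EDS5 (DTX47, AT4G39030, 0.99 ± 0.085) and WRKY18 (AT4G31800, 1.13 ± 0.097). Of splicing factors, 25 of 43 measured were higher, 1 lower and 17 did not pass (25 and 1 adjusted over the list alone) (camera adjusted p = 5.13e-05, adjusted p = 0.0763 with an estimated correlation). They included RSZ22A (AT2G24590, 0.71 ± 0.036), PRL2 (AT3G16650, 0.82 ± 0.066) and SYF2 (AT2G16860, 0.45 ± 0.037). Of miRNA biogenesis, 8 of 10 measured were higher, 1 lower and 1 did not pass (8 and 1 adjusted over the list alone) (camera adjusted p = 0.0091, adjusted p = 0.0763 with an estimated correlation). Genes that passed included SE (AT2G27100, 0.36 ± 0.041), CBP80 (ABH1, AT2G13540, 0.36 ± 0.043) and HST (AT3G05040, 0.42 ± 0.071). Of heat shock and protein folding, 14 of 24 measured were higher, 3 lower and 7 did not pass (14 and 3 adjusted over the list alone) (camera adjusted p = 0.00348, adjusted p = 0.114 with an estimated correlation). Examples were HSP70-4 (MED37C, AT3G12580, 1.17 ± 0.082), BIP3 (MED37B, AT1G09080, 1.8 ± 0.13) and HSP17.6II (HSP17.6, AT5G12020, 1.27 ± 0.12). Of phosphate starvation genes, 7 of 10 measured were higher, 0 lower and 3 did not pass (7 and 0 adjusted over the list alone) (camera adjusted p = 0.00635, adjusted p = 0.312 with an estimated correlation). These took in the phosphatase PS2 (AT1G73010, 1.53 ± 0.12) and SPX1 (AT5G20150, 0.60 ± 0.068).

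The 8 largest increases among genes above 5 FPKM, all of the same sign at each time point, were led by AT1G64795 (chromosome 1, 24082579 to 24082848) at 4.26 ± 0.13, a 19.2-fold difference (adjusted p = 6.32e-13). They took in the plastid transfer RNA gene TRNF (ATCG00410, 4.16 ± 0.35), an unnamed transcript model (3.70 ± 0.081) at chromosome 4, 4990153 to 4991623, the mitochondrial small heat shock protein HSP23.5 (AT5G51440, 3.39 ± 0.13), AT4G12735 (3.34 ± 0.25), the early light-induced protein ELIP2 (AT4G14690, 3.25 ± 0.092), the AAA-ATPase AT2G18193 (3.18 ± 0.086) and the NAC factor anac044 (AT3G01600, 2.92 ± 0.082). ELIP2 (chromosome 4, 8418242 to 8419325) had adjusted p = 4.4e-13. The 8 largest decreases were led by AT1G27565 (chromosome 1, 9574550 to 9575189) at -4.28 ± 0.076, a 19.4-fold difference (adjusted p = 1.04e-14). QQS (AT3G30720) at chromosome 3, 12349047 to 12349933, a gene known to act on starch and protein content, followed at -3.81 ± 0.21 (adjusted p = 4.1e-10). The others were AT4G13577 (-3.47 ± 0.12), AT3G06955 (-3.24 ± 0.21), the apyrase APY5 (AT1G14250, -2.67 ± 0.098), the methylesterase MES18 (AT5G58310, -2.47 ± 0.073), the aldolase FBA5 (AT4G26530, -2.36 ± 0.065) and AT3G62550 (-2.28 ± 0.087). ILP1 itself was at 0.44 ± 0.079 (adjusted p = 0.000194).

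Of 19311 genes tested with limma, 11037 passed at an adjusted p of 0.05 over the 5 time points, 5663 higher and 5374 lower, and 460 of them differed at least 2-fold. With reads scaled to library totals in place of size factors the split was 9205 higher and 3215 lower, so that 74.1% were higher in place of 51.3%. The median of all genes then stood at 0.16 in place of 0.013, and the changes given here are relative to the typical gene. All 13 called lists of 25 kept their direction under both scalings. Of these calls 0 held with an estimated correlation. In the other comparisons such calls held for 5 lists between genotypes at 16 h, 4 at 30 h and 4 in the difference of the changes to 30 h. The other 12 lists were not called, and their members are given as higher, lower and not passing of those measured, with higher and lower adjusted over the list alone in parentheses. They were 7, 2 and 18 of 27 (7 and 2) for the cell cycle, 8, 6 and 3 of 17 (8 and 6) for sucrose and sugar transport, 13, 11 and 10 of 34 (13 and 12) for miRNA target genes, 5, 12 and 9 of 26 (5 and 12) for abscisic acid, drought and cold, 1, 8 and 3 of 12 (1 and 8) for carbon starvation and 6, 6 and 10 of 22 (6 and 7) for jasmonate. Glucosinolate synthesis had 8, 3 and 4 of 15 (8 and 3), guard cell markers 5, 1 and 4 of 10 (5 and 1), vascular markers 4, 2 and 3 of 9 (4 and 2) and meristem and flower markers 2, 1 and 3 of 6 (2 and 3). The circadian clock had 9, 14 and 5 of 28 (9 and 14) and photoprotection 8, 9 and 4 of 21 (8 and 9), which turned with total-read scaling to 11 higher and 10 lower, and 11 and 8. In the last list ELIP2, ELIP1 (AT3G22840, 2.63 ± 0.059) and GPX7 (AT4G31870, 1.19 ± 0.056) were higher and the superoxide dismutase CSD2 (AT2G28190, -1.36 ± 0.04) was lower.

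**Figure D2:**
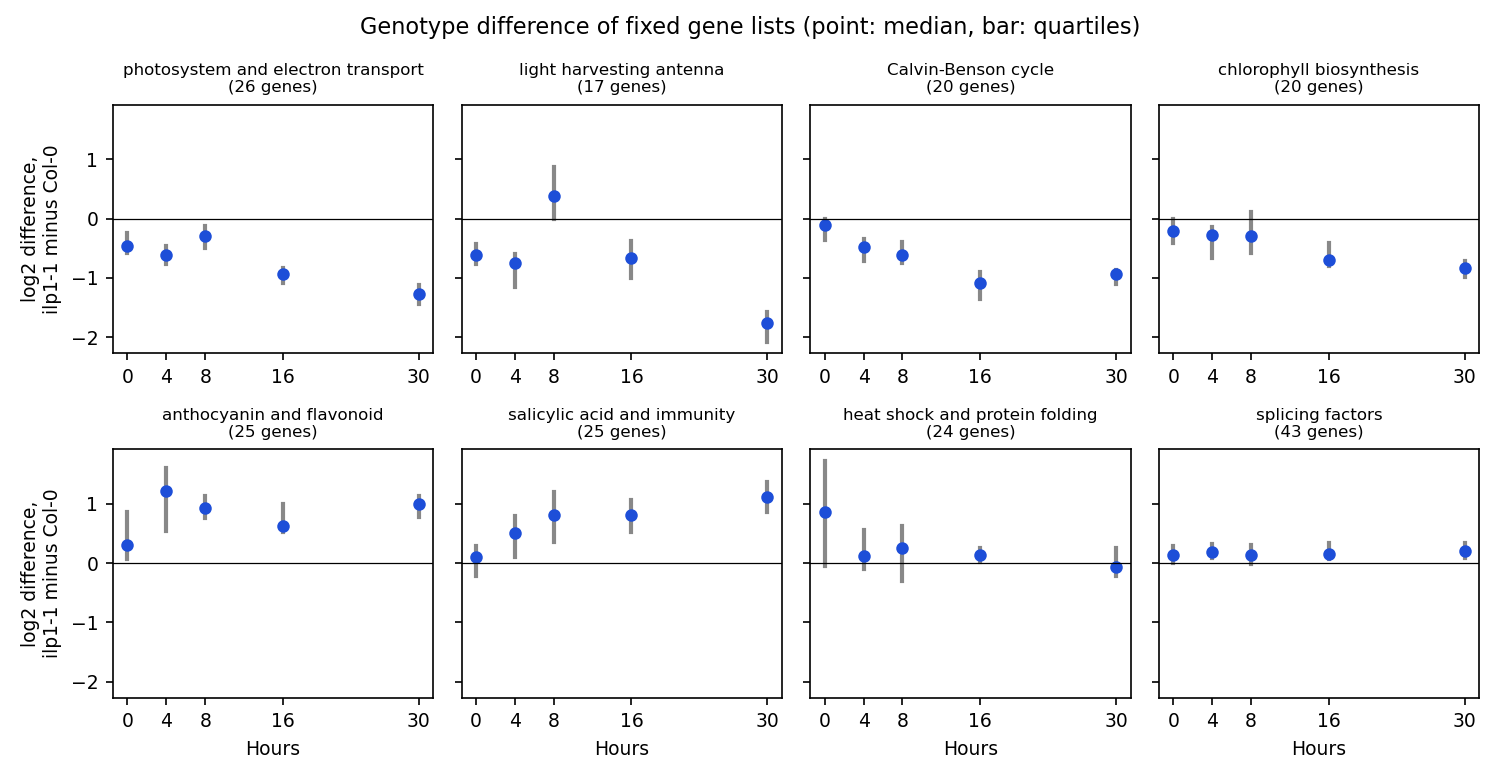
Median log2 difference between ilp1-1 and Col-0 (linear axis) for 8 fixed gene lists at each time point, with bars from the lower to the upper quartile of the measured members. The photosystem medians lie under 0 at all 5 time points, and the antenna median lies above 0 at 8 h, at 0.38.

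At 0 h, before high light, the question is how the genotypes differed under growth light (2 libraries against 2). The highest calls were AT4G12735 (6.54 ± 0.55), AT2G41730 (5.80 ± 0.26), HSP23.5 (5.75 ± 0.30) and the transfer RNA precursor AT5G43455 (5.01 ± 0.46), beside ILP1 at 1.09 ± 0.18. The lowest were AT4G13577 (-4.66 ± 0.26), AT1G27565 (-4.14 ± 0.17), QQS (-3.76 ± 0.46) and the zinc finger gene ATCTH (AT2G25900, -2.80 ± 0.22). Heat shock and folding genes were higher in the libraries labelled ilp1-1, with HSP17.6II (4.27 ± 0.26), HSP17.6A (HSP17.7, AT5G12030, 3.88 ± 0.38) and HSP70-4 (3.07 ± 0.18). In that list 13 of 24 measured were higher, 2 lower and 9 did not pass (14 and 2 adjusted over the list alone) (camera adjusted p = 6.72e-07, adjusted p = 0.0547 with an estimated correlation). Carbon starvation markers were lower, among them the trehalose-phosphate synthase genes TPS11 (AT2G18700, -2.2 ± 0.20) and TPS8 (AT1G70290, -1.71 ± 0.18) and SEN1 (STR15, AT4G35770, -1.85 ± 0.21). There 0 of 12 measured were higher, 6 lower and 6 did not pass (0 and 8 adjusted over the list alone) (camera adjusted p = 6.6e-06, adjusted p = 0.135 with an estimated correlation). Of the photosystem list 0 of 26 measured were higher, 22 lower and 4 did not pass (0 and 23 adjusted over the list alone), with PSBO2 (-0.67 ± 0.045) and PSBO1 (-0.57 ± 0.05) (camera adjusted p = 4.29e-13, adjusted p = 0.0868 with an estimated correlation), and of the antenna list 0 of 17 measured were higher, 16 lower and 1 did not pass (0 and 17 adjusted over the list alone) (camera adjusted p = 7.17e-13, adjusted p = 0.135 with an estimated correlation). In all, 4292 genes passed, 1934 higher and 2358 lower, against 3160 and 1669 with total-read scaling (65.4% higher in place of 45.1%). The count was 2508 without Col-0 0 h replicate 2 and 1565 with only these 4 libraries in the fit.

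After 4 h of high light the genotypes differed in most plastid-encoded genes. Of this group, put together only after the data were seen, 99 of 108 were higher in the libraries labelled ilp1-1, with a median of 2.97. TRNF (8.20 ± 0.78), TRNL.1 (ATCG00400, 7.12 ± 1.03), PSBZ (ATCG00300, 6.76 ± 0.45) and TRNS.2 (ATCG00290, 6.56 ± 0.86) were the highest calls, and ILP1 stood at 0.51 ± 0.18. The nuclear photosystem genes went the other way, and there 0 of 26 measured were higher, 25 lower and 1 did not pass (0 and 25 adjusted over the list alone) (camera adjusted p = 1.46e-16, adjusted p = 0.108 with an estimated correlation). Some of these were FNR2 (-1.84 ± 0.056) and PSAD1 (-0.75 ± 0.049). In the same libraries, with plastid read shares of 0.203 and 0.453%, the antenna list gave 0 of 17 higher, 17 lower, 0 not passing, 0 and 17 adjusted over the list alone (camera adjusted p = 7.74e-15, adjusted p = 0.108 with an estimated correlation). Chlorophyll synthesis was led by PORB (-3.35 ± 0.09), and there 1 of 20 measured were higher, 13 lower and 6 did not pass (1 and 15 adjusted over the list alone) (camera adjusted p = 2.67e-05, adjusted p = 0.108 with an estimated correlation). Anthocyanin genes were higher, with PAP2 (4.11 ± 0.33) and FLS1 (2.05 ± 0.10), and 19 of 25 measured were higher, 1 lower and 5 did not pass (20 and 1 adjusted over the list alone) (camera adjusted p = 2.8e-13, adjusted p = 0.108 with an estimated correlation). Cold and drought genes were lower, with COR15B (AT2G42530, -3.86 ± 0.17), COR15A (AT2G42540, -3.02 ± 0.17) and KIN2 (AT5G15970, -1.88 ± 0.11), and 3 of 26 measured were higher, 12 lower and 11 did not pass (3 and 12 adjusted over the list alone) (camera adjusted p = 0.00275, adjusted p = 0.429 with an estimated correlation). The lowest calls besides COR15B were AT1G27565 (-4.76 ± 0.17), AT4G13577 (-4.21 ± 0.26) and an unnamed transcript model (-4.11 ± 0.21) at chromosome 1, 25990205 to 25992306. In all, 5900 genes passed, 2842 higher and 3058 lower. Total-read scaling gave 4914 and 2021 (70.9% in place of 48.2% higher, the median of all genes at 0.14). Fitted on these 4 libraries alone the count was 3878.

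By 8 h the antenna list stood higher in the libraries labelled ilp1-1. There 12 of 17 measured were higher, 3 lower and 2 did not pass (12 and 4 adjusted over the list alone) (camera adjusted p = 0.000768, adjusted p = 0.454 with an estimated correlation). Among them were LHCB1.1 (AT1G29920, 1.32 ± 0.055) and LHCB2.2 (AT2G05070, 1.48 ± 0.12) higher and LHCB4.3 (AT2G40100, -1.14 ± 0.074) lower. The plastid read share of these libraries was 0.0995 and 0.129%. Photosystem and Calvin-Benson genes stayed lower, the former with 1 of 26 higher, 19 lower, 6 not passing, 3 and 19 adjusted over the list alone (camera adjusted p = 3.15e-06, adjusted p = 0.32 with an estimated correlation) and the latter with 0 of 20 higher, 17 lower, 3 not passing, 0 and 18 adjusted over the list alone (camera adjusted p = 1.62e-13, adjusted p = 0.3 with an estimated correlation). Photoprotection genes were higher, with ELIP2 (5.29 ± 0.21), ELIP1 (2.96 ± 0.13) and the glutathione peroxidase-like GPX7 (2.54 ± 0.12), and 10 of 21 measured were higher, 5 lower and 6 did not pass (11 and 5 adjusted over the list alone) (camera adjusted p = 0.0406, adjusted p = 0.454 with an estimated correlation). Immunity genes were higher too, with PAD3 (CYP71B15, AT3G26830, 2.37 ± 0.39), of camalexin synthesis, and WRKY46 (2.1 ± 0.21), and 12 of 25 measured were higher, 0 lower and 13 did not pass (13 and 0 adjusted over the list alone) (camera adjusted p = 2.54e-05, adjusted p = 0.454 with an estimated correlation). The highest calls besides ELIP2 were the plastid genes TRNF (5.30 ± 0.78), PSBZ (5.21 ± 0.45) and TRNL.1 (4.99 ± 1.03), and the lowest AT1G27565 (-4.01 ± 0.17), QQS (-4.0 ± 0.46), MES18 (-3.10 ± 0.16) and AT3G06955 (-2.96 ± 0.48). ILP1 did not pass (0.47 ± 0.18). Over the alternatives the adjusted p of TRNF ran from 1.73e-05 to 0.0762, and limma-voom on the recovered reads ended its call. In all, 5700 genes passed, 2762 higher and 2938 lower. Total-read scaling gave 3910 and 2283 (63.1% in place of 48.5% higher). Without ilp1-1 8 h replicate 2 the count was 3767.

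At 16 h the photosynthesis groups were lower together. For photosystems 0 of 26 measured were higher, 26 lower and 0 did not pass (0 and 26 adjusted over the list alone), with PSBO2 (-1.33 ± 0.045) and PSBQ1 (AT4G21280, -1.15 ± 0.049) (camera adjusted p = 2.76e-25, adjusted p = 0.0222 with an estimated correlation). For the Calvin-Benson cycle 0 of 20 measured were higher, 20 lower and 0 did not pass (0 and 20 adjusted over the list alone), with RBCS2B (-1.89 ± 0.055) and RCA (AT2G39730, -1.65 ± 0.069) (camera adjusted p = 5.26e-25, adjusted p = 0.0222 with an estimated correlation). Photorespiration gave 0 of 16 higher, 16 lower, 0 not passing, 0 and 16 adjusted over the list alone (camera adjusted p = 1.85e-18, adjusted p = 0.0274 with an estimated correlation). An example was GGT1 (GGAT1, AT1G23310, -0.99 ± 0.044). In photoprotection 3 of 21 measured were higher, 13 lower and 5 did not pass (4 and 13 adjusted over the list alone) (camera adjusted p = 0.000224, adjusted p = 0.157 with an estimated correlation). They included CSD2 (-1.76 ± 0.089) and PRXQ (ATPRX Q, AT3G26060, -0.99 ± 0.061). The highest calls were AT1G64795 (4.17 ± 0.28), an unnamed transcript model (3.65 ± 0.18) on chromosome 4, TRNF (3.18 ± 0.78) and TRNS.2 (2.79 ± 0.86), and the lowest AT1G27565 (-4.21 ± 0.17), AT3G06955 (-4.0 ± 0.48), QQS (-3.74 ± 0.46) and APY5 (-2.92 ± 0.22). At 16 h ILP1 did not pass (0.013 ± 0.18). Over the alternatives the adjusted p ran from 0.00235 to 0.448 for TRNF, whose call limma-voom on the recovered reads ended, and from 0.00395 to 0.423 for TRNS.2. The call of TRNS.2 ended with limma-voom, without a filter, on these 4 libraries alone, without Col-0 16 h replicate 1 (1.91) and without ilp1-1 16 h replicate 1 (2.3). In all, 5343 genes passed, 2122 higher and 3221 lower. With total-read scaling these were 6199 and 1735 (78.1% in place of 39.7% higher), with the median of all genes at 0.23. The count was 3528 without ilp1-1 16 h replicate 2 and 3514 on these 4 libraries alone.

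At 30 h, after the return to normal light, photosynthesis transcripts were again lower in the libraries labelled ilp1-1. Photosystem genes gave 0 of 26 higher, 26 lower, 0 not passing, 0 and 26 adjusted over the list alone, with PSAD1 (-1.41 ± 0.049) and PSBQ2 (AT4G05180, -1.95 ± 0.071) (camera adjusted p = 8.66e-30, adjusted p = 0.0137 with an estimated correlation). Antenna genes gave 0 of 17 higher, 17 lower, 0 not passing, 0 and 17 adjusted over the list alone, with LHCB1.1 (-2.88 ± 0.055) (camera adjusted p = 1.31e-24, adjusted p = 0.0271 with an estimated correlation). Immunity genes were higher, with WRKY18 (1.60 ± 0.22) and EDS1 (AT3G48090, 1.09 ± 0.15), and 18 of 25 measured were higher, 0 lower and 7 did not pass (21 and 0 adjusted over the list alone) (camera adjusted p = 1.97e-07, adjusted p = 0.311 with an estimated correlation). In nitrogen assimilation 3 of 30 measured were higher, 13 lower and 14 did not pass (3 and 14 adjusted over the list alone) (camera adjusted p = 0.000863, adjusted p = 0.118 with an estimated correlation). Genes that passed included GS2 (-1.02 ± 0.072) and NIR1 (-1.39 ± 0.10). The photoprotection list was called lower, with 4 of 21 higher, 10 lower, 7 not passing, 5 and 10 adjusted over the list alone, but with total-read scaling its median turned to 0.069, with 8 members higher and 9 lower (camera adjusted p = 0.0433, adjusted p = 0.451 with an estimated correlation). The highest calls were AT1G64795 (4.56 ± 0.28), an unnamed transcript model (3.56 ± 0.18) on chromosome 4, AT2G23910 (2.85 ± 0.25) and AT2G44240 (2.71 ± 0.90). The lowest were AT1G27565 (-4.27 ± 0.17), AT3G06955 (-4.15 ± 0.48), FBA5 (-4.09 ± 0.14) and QQS (-3.74 ± 0.46), and ILP1 did not pass (0.12 ± 0.18). The adjusted p of AT2G44240 ran from 0.00859 to 0.316 over the alternatives. Its call ended with a pseudocount of 0.1, without a filter, without the trend, on these 4 libraries alone, and without Col-0 30 h replicate 1 (3.15), Col-0 30 h replicate 2 (2.26) or ilp1-1 30 h replicate 2 (1.47). In all, 6573 genes passed, 3320 higher and 3253 lower. Total-read scaling gave 6642 and 2060 (76.3% in place of 50.5% higher, the median of all genes at 0.23). On these 4 libraries alone the count was 3974.

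**Figure D3:**
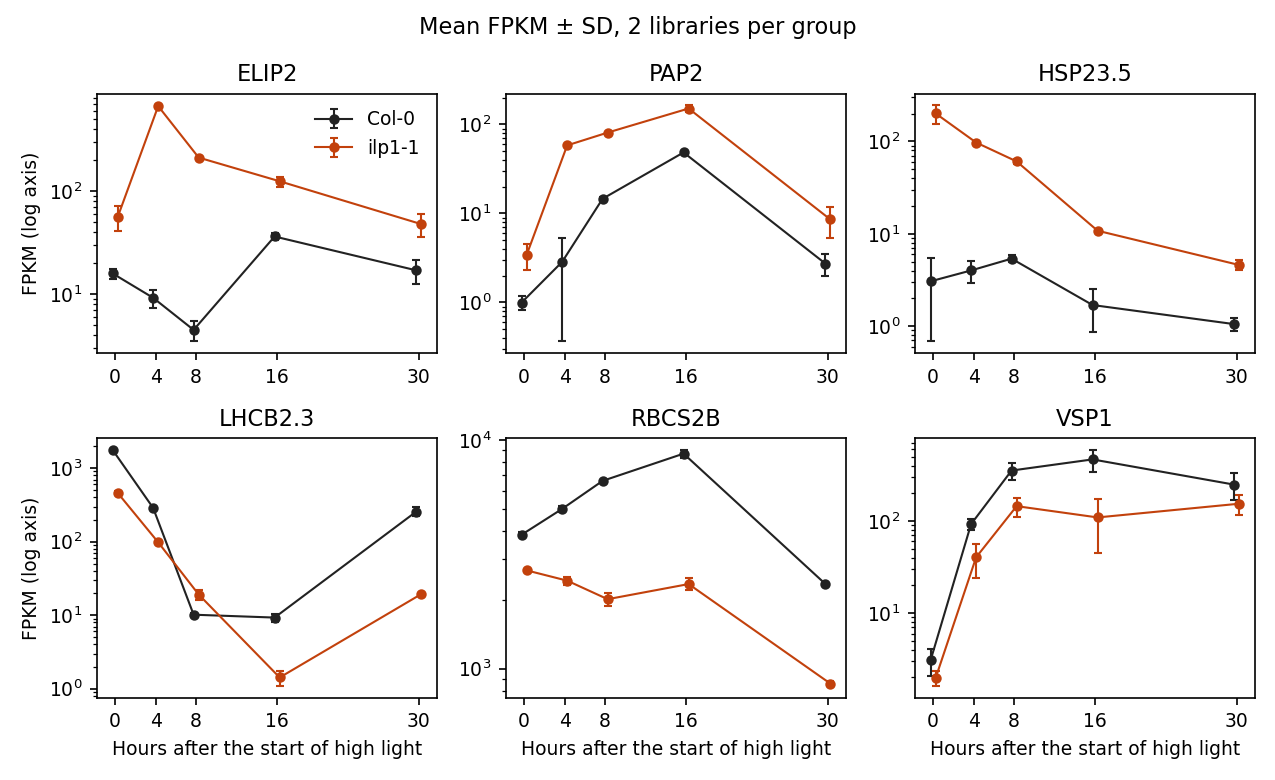
Mean FPKM (log axis) of 6 genes against hours after the start of high light, with bars of 1 SD over 2 libraries per group. ELIP2 differs by 5.29 ± 0.21 on the log2 scale at 8 h, and VSP1 rises in both genotypes.

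The wild type series asks how Col-0 leaves changed from 0 h on. No libraries of leaves kept in normal light at the same hours were used here, so the changes hold both the light and the time of day. After 4 h of high light the largest increases above 5 FPKM were the clock-regulated RNA-binding protein GRP7 (RBG7, AT2G21660, 5.43 ± 0.094) at chromosome 2, 9265084 to 9266557, AT1G56300 (5.07 ± 0.14), the clock gene ELF4 (AT2G40080, 4.89 ± 0.17), the chloroplast chaperone DJC76 (AT5G23240, 4.78 ± 0.16), OEP161 (AT2G28900, 4.73 ± 0.093) of the outer envelope, the vegetative storage protein VSP1 (AT5G24780, 4.53 ± 0.37), the protease inhibitor AT1G73325 (4.51 ± 0.25) and the glucose-6-phosphate translocator GPT2 (AT1G61800, 4.36 ± 0.20). GRP7 rose 43.2-fold (adjusted p = 7.21e-15). The largest decreases were the morning clock gene LHY (AT1G01060, -5.05 ± 0.14) at chromosome 1, 33365 to 37871, NAC029 (AT1G69490, -4.84 ± 0.25), AT5G48490 (-4.48 ± 0.31), AT2G41250 (-4.40 ± 0.28), AT5G19190 (-3.93 ± 0.26), ATCTH (-3.89 ± 0.22), GASA6 (AT1G74670, -3.61 ± 0.18) and AT3G06070 (-3.51 ± 0.21). LHY fell 33-fold (adjusted p = 8.37e-13). ILP1 did not pass (-0.035 ± 0.18, adjusted p = 0.893).

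Starch metabolism rose at 4 h in Col-0 (2 libraries against 2). In that list 27 of 34 measured rose, 3 fell and 4 did not pass (28 and 3 adjusted over the list alone) (camera adjusted p = 1.29e-14, adjusted p = 0.199 with an estimated correlation). Examples were the breakdown genes BAM3 (AT4G17090, 2.39 ± 0.058), SEX4 (DSP4, AT3G52180, 2.96 ± 0.087), GWD1 (AT1G10760, 2.99 ± 0.091), PHS2 (AT3G46970, 3.66 ± 0.12) and ISA3 (AT4G09020, 4.25 ± 0.14). Anthocyanin genes rose as well, with the regulators MYB111 (AT5G49330, 2.08 ± 0.16) and PAP1 (MYB75, AT1G56650, 1.93 ± 0.18), and 18 of 25 measured rose, 1 fell and 6 did not pass (19 and 1 adjusted over the list alone) (camera adjusted p = 8.8e-06, adjusted p = 0.429 with an estimated correlation). Jasmonate genes followed VSP1, with the allene oxide cyclase AOC2 (AT3G25770, 2.50 ± 0.11), and 12 of 22 measured rose, 0 fell and 10 did not pass (12 and 0 adjusted over the list alone) (camera adjusted p = 0.000174, adjusted p = 0.429 with an estimated correlation). Of the splicing factors 22 of 43 measured rose, 2 fell and 19 did not pass (22 and 2 adjusted over the list alone) (camera adjusted p = 0.000688, adjusted p = 0.229 with an estimated correlation). These took in PRMT5 (PMRT15, AT4G31120, 1.52 ± 0.10) and LSM8 (AT1G65700, 1.11 ± 0.11). In the Calvin-Benson cycle 13 of 20 measured rose, 4 fell and 3 did not pass (15 and 4 adjusted over the list alone) (camera adjusted p = 0.0281, adjusted p = 0.702 with an estimated correlation). Some of these were RPI3 (AT3G04790, 0.81 ± 0.058) and RBCS1B (RBCS-1B, AT5G38430, 1.14 ± 0.092). Antenna genes fell, with LHCB2.3 (LHCB2.4, AT3G27690, -2.61 ± 0.12), LHCB4.2 (AT3G08940, -1.82 ± 0.09) and LHCB1.1 (-1.0 ± 0.055), and 1 of 17 measured rose, 15 fell and 1 did not pass (1 and 15 adjusted over the list alone) (camera adjusted p = 2.9e-07, adjusted p = 0.355 with an estimated correlation). Photosystem genes fell on balance, with PSAD2 (AT1G03130, -1.37 ± 0.077), and 2 of 26 measured rose, 19 fell and 5 did not pass (3 and 19 adjusted over the list alone), while the ferredoxin reductase FNR2 (1.44 ± 0.056) rose (camera adjusted p = 0.00029, adjusted p = 0.429 with an estimated correlation). Carbon starvation markers fell, with TPS8 (-3.22 ± 0.18), TPS11 (-2.33 ± 0.20) and SEN1 (-1.98 ± 0.21), and 0 of 12 measured rose, 9 fell and 3 did not pass (0 and 9 adjusted over the list alone) (camera adjusted p = 4.16e-05, adjusted p = 0.229 with an estimated correlation). Immunity genes fell, with WRKY70 (AT3G56400, -1.84 ± 0.16), and 0 of 25 measured rose, 17 fell and 8 did not pass (0 and 17 adjusted over the list alone) (camera adjusted p = 5.82e-05, adjusted p = 0.553 with an estimated correlation). Heat shock genes fell, with MBF1C (AT3G24500, -2.00 ± 0.13) and HSP90.1 (HSP90-1, AT5G52640, -2.52 ± 0.24), and 2 of 24 measured rose, 13 fell and 9 did not pass (2 and 13 adjusted over the list alone) (camera adjusted p = 0.00327, adjusted p = 0.229 with an estimated correlation). In all, 8898 of 19311 genes passed, 4361 risen and 4537 fallen, 2349 at least 2-fold.

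After 8 h in Col-0 the antenna genes had fallen, with LHCB2.3 (-7.31 ± 0.12) and LHCB1.4 (LHB1B1, AT2G34430, -6.94 ± 0.21). In that list 1 of 17 measured rose, 16 fell and 0 did not pass (1 and 16 adjusted over the list alone), with a median of -2.81 (camera adjusted p = 1.69e-15, adjusted p = 0.164 with an estimated correlation). Of the photosystem genes 2 of 26 measured rose, 23 fell and 1 did not pass (2 and 23 adjusted over the list alone) (camera adjusted p = 1.51e-11, adjusted p = 0.164 with an estimated correlation). The evening gene ELF4 (8.02 ± 0.17) rose beside GRP7 (7.36 ± 0.094), DJC76 (6.98 ± 0.16) and VSP1 (6.45 ± 0.37), and CCA1 (AT2G46830, -6.03 ± 0.17), a morning clock gene, fell with AT5G48490 (-6.59 ± 0.31). Anthocyanin genes rose, with MYB111 (3.76 ± 0.16), TT5 (CHI1, AT3G55120, 1.66 ± 0.081) and TT4 (1.85 ± 0.096), and 22 of 25 measured rose, 1 fell and 2 did not pass (22 and 1 adjusted over the list alone) (camera adjusted p = 6.85e-12, adjusted p = 0.207 with an estimated correlation). The abscisic acid, drought and cold list fell on balance, with 6 of 26 risen, 16 fallen, 4 not passing, 6 and 16 adjusted over the list alone, although COR15B (3.76 ± 0.17), a plastid cold-acclimation protein, rose (camera adjusted p = 0.0391, adjusted p = 0.621 with an estimated correlation). ILP1 did not pass (0.038 ± 0.18). In all, 9666 genes passed, 4812 risen and 4854 fallen, 3073 at least 2-fold.

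At 16 h in Col-0 the lowest values were all antenna genes, LHCB1.4 (-7.98 ± 0.21), LHCB1.1 (-7.53 ± 0.055), LHCB2.3 (-7.43 ± 0.12) and LHCB2.2 (-7.21 ± 0.12). Of that list 1 of 17 measured rose, 16 fell and 0 did not pass (1 and 16 adjusted over the list alone) (camera adjusted p = 5.08e-21, adjusted p = 0.104 with an estimated correlation). The flavonoid hydroxylase TT7 (6.01 ± 0.24) led the anthocyanin genes, of which 23 of 25 measured rose, 1 fell and 1 did not pass (23 and 1 adjusted over the list alone) (camera adjusted p = 3.31e-18, adjusted p = 0.104 with an estimated correlation). AT2G23910 (7.89 ± 0.25), VSP1 (6.84 ± 0.37), the cellulose synthase-like ATCSLA01 (AT4G16590, 6.79 ± 0.24) and AT1G73325 (6.38 ± 0.25) had the highest values. In the abscisic acid, drought and cold list 0 of 26 measured rose, 18 fell and 8 did not pass (0 and 19 adjusted over the list alone) (camera adjusted p = 3.33e-06, adjusted p = 0.279 with an estimated correlation). Among them were ERD14 (AT1G76180, -1.97 ± 0.08), RD22 (AT5G25610, -1.45 ± 0.087) and GOLS2 (AT1G56600, -3.36 ± 0.28). The photorespiration list rose, with DIT2.1 (DIT2-1, AT5G64290, 0.82 ± 0.081) and GDCT (0.52 ± 0.056), and 11 of 16 measured rose, 3 fell and 2 did not pass (11 and 3 adjusted over the list alone) (camera adjusted p = 0.0424, adjusted p = 0.59 with an estimated correlation). ILP1 did not pass (0.066 ± 0.18). In all, 8104 genes passed, 4281 risen and 3823 fallen, 2294 at least 2-fold.

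By 30 h, with 6 h of normal light after the high light, immunity genes had risen in Col-0. They included the salicylic acid transporter EDS5 (2.17 ± 0.19), the isochorismate synthase ICS1 (EDS16, AT1G74710, 2.00 ± 0.20) and NUDT6 (AT2G04450, 2.80 ± 0.29), and 20 of 25 measured rose, 0 fell and 5 did not pass (22 and 0 adjusted over the list alone) (camera adjusted p = 2.04e-07, adjusted p = 0.354 with an estimated correlation). Glucosinolate genes fell, with the regulator MYB29 (AT5G07690, -1.70 ± 0.10), and 1 of 15 measured rose, 11 fell and 3 did not pass (1 and 11 adjusted over the list alone) (camera adjusted p = 2.52e-05, adjusted p = 0.287 with an estimated correlation). Of the guard cell markers 0 of 10 measured rose, 6 fell and 4 did not pass (0 and 6 adjusted over the list alone) (camera adjusted p = 0.0078, adjusted p = 0.354 with an estimated correlation). An example was MYB60 (AT1G08810, -1.8 ± 0.23). Antenna genes stayed below their level at 0 h, with 1 of 17 risen, 16 fallen, 0 not passing, 1 and 16 adjusted over the list alone, while LHCB4.3 (2.3 ± 0.074) was the member that rose (camera adjusted p = 1.22e-11, adjusted p = 0.287 with an estimated correlation). The highest values were VSP1 (5.92 ± 0.37), GRP7 (4.04 ± 0.094), VSP2 (AT5G24770, 3.76 ± 0.38) and the transfer RNA precursor AT5G60285 (3.70 ± 0.62), and the lowest AT5G48490 (-4.61 ± 0.31), the expansin EXPB1 (AT2G20750, -4.35 ± 0.23), AT5G03395 (-4.34 ± 0.30) and AT1G13650 (-3.62 ± 0.11). The ILP1 change at 30 h did not pass (-0.13 ± 0.18). In all, 7811 genes passed, 4015 risen and 3796 fallen. Total-read scaling gave 5033 and 2992 (62.7% in place of 51.4% risen).

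The series of ilp1-1 asks the same of the mutant, again with no normal-light libraries used. ILP1 fell from its level at 0 h in the libraries labelled ilp1-1, with -0.62 ± 0.18 at 4 h, -0.59 ± 0.18 at 8 h, -1.01 ± 0.18 at 16 h and -1.11 ± 0.18 at 30 h. The call ended at 4 h (adjusted p from 0.00114 to 0.101 over the alternatives) without ilp1-1 0 h replicate 2 (-0.48) or ilp1-1 4 h replicate 1 (-0.58). At 8 h (0.0023 to 0.114) it ended without ilp1-1 0 h replicate 2 (-0.45) or ilp1-1 8 h replicate 1 (-0.54). At 4 h the plastid genes TRNS.2 (6.75 ± 0.86), PSBZ (6.12 ± 0.45), TRNL.1 (5.95 ± 1.03) and PSBL (ATCG00560, 5.33 ± 0.59) rose most. The hydrolase-like AT2G41250 (-4.70 ± 0.28), AT5G43455 (-4.57 ± 0.46), GASA6 (-4.56 ± 0.18) and HSP17.6A (-4.48 ± 0.38) fell most. Anthocyanin genes rose, with MYB111 (3.10 ± 0.16), FLS1 (1.76 ± 0.10) and TT4 (1.59 ± 0.096), and 21 of 25 measured rose, 1 fell and 3 did not pass (21 and 1 adjusted over the list alone) (camera adjusted p = 1.3e-12, adjusted p = 0.134 with an estimated correlation). Heat shock genes fell, and there 3 of 24 measured rose, 16 fell and 5 did not pass (4 and 18 adjusted over the list alone) (camera adjusted p = 4.78e-07, adjusted p = 0.0568 with an estimated correlation). Antenna and photosystem genes fell while the plastid read share stood at 0.203 and 0.453%, the antenna with 1 of 17 risen, 16 fallen, 0 not passing, 1 and 16 adjusted over the list alone (camera adjusted p = 5.22e-11, adjusted p = 0.134 with an estimated correlation) and the photosystems with 0 of 26 risen, 22 fallen, 4 not passing, 0 and 22 adjusted over the list alone (camera adjusted p = 1.49e-09, adjusted p = 0.134 with an estimated correlation). In all, 7913 genes passed, 3977 risen and 3936 fallen, 2010 at least 2-fold.

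At 8 h in ilp1-1 the clock genes ELF4 (6.54 ± 0.17), LHY (-6.16 ± 0.14) and CCA1 (-5.17 ± 0.17) were among the largest changes, with GRP7 (6.65 ± 0.094), AT4G18422 (6.40 ± 0.40) and AT2G23910 (6.10 ± 0.25) risen and AT5G48490 (-5.30 ± 0.31) and GASA6 (-5.05 ± 0.18) fallen. Of the jasmonate list 17 of 22 measured rose, 0 fell and 5 did not pass (18 and 0 adjusted over the list alone) (camera adjusted p = 6.95e-07, adjusted p = 0.184 with an estimated correlation). They included AOC2 (3.20 ± 0.11) and OPR3 (AT2G06050, 2.3 ± 0.14). Of the anthocyanin list 22 of 25 measured rose, 0 fell and 3 did not pass (22 and 0 adjusted over the list alone) (camera adjusted p = 1.89e-14, adjusted p = 0.115 with an estimated correlation). Genes that passed included TT19 (GSTF12, AT5G17220, 3.96 ± 0.16) and TT4 (2.2 ± 0.096). Photosystem genes fell, with PSAD2 (-2.25 ± 0.077) and PSAN (AT5G64040, -2.08 ± 0.071), and 1 of 26 measured rose, 25 fell and 0 did not pass (1 and 25 adjusted over the list alone) (camera adjusted p = 2.58e-13, adjusted p = 0.109 with an estimated correlation). Antenna genes gave 1 of 17 risen, 16 fallen, 0 not passing, 1 and 16 adjusted over the list alone (camera adjusted p = 7.26e-14, adjusted p = 0.113 with an estimated correlation), with plastid reads at 0.0995 and 0.129%. Of the Calvin-Benson list 2 of 20 measured rose, 11 fell and 7 did not pass (2 and 11 adjusted over the list alone) (camera adjusted p = 0.0125, adjusted p = 0.538 with an estimated correlation). Examples were GAPA (GAPA1, AT3G26650, -1.28 ± 0.05) and RCA (-1.66 ± 0.069). In all, 9068 genes passed, 4595 risen and 4473 fallen, 2898 at least 2-fold.

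By 16 h in ilp1-1 LHCB2.3 (-7.58 ± 0.12), LHCB1.1 (-7.51 ± 0.055), LHCB2.2 (-7.32 ± 0.12) and LHCB2.1 (AT2G05100, -7.17 ± 0.10) had fallen most, and the antenna list gave 1 of 17 risen, 16 fallen, 0 not passing, 1 and 16 adjusted over the list alone (camera adjusted p = 2.36e-20, adjusted p = 0.054 with an estimated correlation). Photosystem genes fell, with PSAN (-3.45 ± 0.071) and PSAD2 (-3.71 ± 0.077), and 1 of 26 measured rose, 25 fell and 0 did not pass (1 and 25 adjusted over the list alone) (camera adjusted p = 4.86e-21, adjusted p = 0.0509 with an estimated correlation). AT2G23910 (7.26 ± 0.25), TT7 (6.94 ± 0.24), the non-coding AT3G25795 (6.52 ± 0.20) and ELF4 (5.79 ± 0.17) rose most. Photorespiration fell, with GGT1 (-1.09 ± 0.044) and CAT2 (-1.35 ± 0.074), and 0 of 16 measured rose, 13 fell and 3 did not pass (0 and 13 adjusted over the list alone) (camera adjusted p = 1.71e-05, adjusted p = 0.295 with an estimated correlation). Immunity genes rose, with EDS5 (1.43 ± 0.19) and EDS1 (0.95 ± 0.15), and 13 of 25 measured rose, 1 fell and 11 did not pass (13 and 1 adjusted over the list alone) (camera adjusted p = 0.0134, adjusted p = 0.574 with an estimated correlation). In all, 8451 genes passed, 4189 risen and 4262 fallen. Total-read scaling gave 6544 and 2866 (69.5% in place of 49.6% risen, the median of all genes at 0.19).

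At 30 h in ilp1-1 immunity genes had risen, with PR2 (BGL2, AT3G57260, 4.61 ± 0.45) and NUDT6 (4.07 ± 0.29), and so had VSP1 (5.69 ± 0.37) and the lipid-transfer protein LTP4 (AT5G59310, 4.08 ± 0.67). Of that list 24 of 25 measured rose, 0 fell and 1 did not pass (24 and 0 adjusted over the list alone) (camera adjusted p = 1.26e-10, adjusted p = 0.231 with an estimated correlation). The heat shock genes HSP23.5 (-5.16 ± 0.30), HSP17.6II (-4.86 ± 0.26) and HSP70-4 (-4.86 ± 0.18) fell most, with the antenna gene LHCB2.3 (-4.50 ± 0.12). Of the heat shock list 4 of 24 measured rose, 17 fell and 3 did not pass (4 and 17 adjusted over the list alone) (camera adjusted p = 3.76e-05, adjusted p = 0.0798 with an estimated correlation). Photosystem genes fell, with PSAN (-2.75 ± 0.071) and PSBQ2 (-2.58 ± 0.071), and 0 of 26 measured rose, 26 fell and 0 did not pass (0 and 26 adjusted over the list alone) (camera adjusted p = 1.03e-19, adjusted p = 0.078 with an estimated correlation). Guard cell markers gave 0 of 10 risen, 8 fallen, 2 not passing, 0 and 9 adjusted over the list alone (camera adjusted p = 0.00521, adjusted p = 0.298 with an estimated correlation), and vascular markers, not called, 0 of 9 risen, 6 fallen, 3 not passing, 0 and 6 adjusted over the list alone (camera adjusted p = 0.116, adjusted p = 0.611 with an estimated correlation). Glucosinolate genes fell, with MYB29 (-2.07 ± 0.10) and MYB34 (AT5G60890, -2.54 ± 0.13), and 1 of 15 measured rose, 13 fell and 1 did not pass (1 and 13 adjusted over the list alone) (camera adjusted p = 4.33e-07, adjusted p = 0.118 with an estimated correlation). In all, 10056 genes passed, 5326 risen and 4730 fallen. Total-read scaling gave 7576 and 3362 (69.3% in place of 53% risen, the median of all genes at 0.21).

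More genes responded alike in both genotypes, whose libraries are separate, than chance predicted. At 4 h 2880 genes rose in both, where 898 were predicted by chance, and 2721 fell in both against 925. At 8 h the shared counts were 3390 risen (1145 by chance) and 3141 fallen (1124), at 16 h 2786 (929) and 2554 (844), and at 30 h 2875 (1107) and 2819 (930). Genes with opposite calls numbered 178 at 4 h, 235 at 8 h, 296 at 16 h and 285 at 30 h. In Col-0 alone 3119, 2900, 2468 and 1832 genes passed at 4, 8, 16 and 30 h, and in ilp1-1 alone 2134, 2302, 2815 and 4077, which does not test whether their changes differed. Across genes the changes of both genotypes had a Pearson correlation of 0.712 at 4 h, 0.790 at 8 h, 0.773 at 16 h and 0.744 at 30 h, and genes are not independent replicates.

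**Figure D4:**
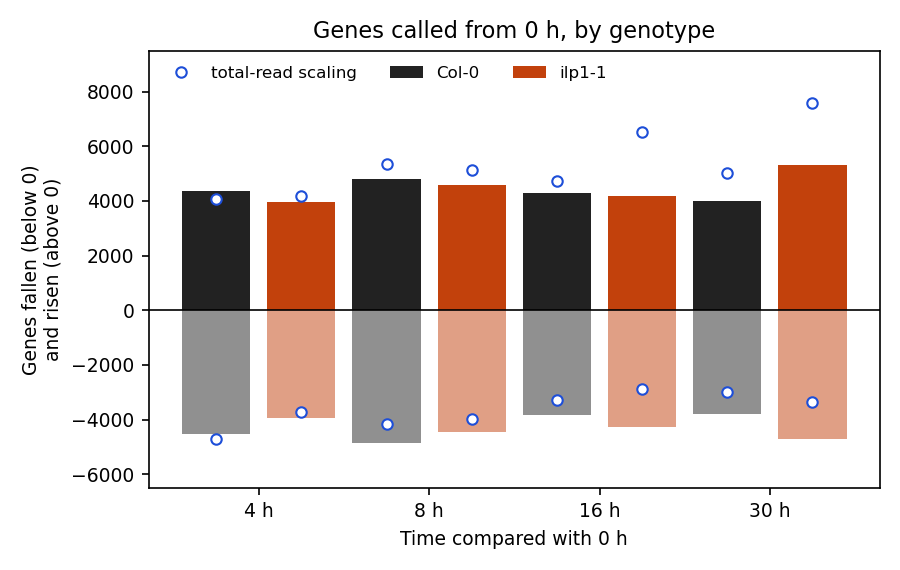
Genes risen (above 0) and fallen (below 0) from 0 h at an adjusted p of 0.05, by genotype and hour, on a linear axis. Hollow marks give the same counts with total-read scaling, such as 7576 risen in ilp1-1 at 30 h in place of 5326.

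Differences between ilp1-1 and Col-0 in the change from 0 h (4 groups of 2) all subtract the same 0 h gap, wide for AT5G43455 and ILP1. At 4 h anthocyanin genes rose more in ilp1-1, with FLS1 (1.11 ± 0.15) and PAP2 (2.98 ± 0.46). There 9 of 25 measured were higher, 0 lower and 16 did not pass (18 and 0 adjusted over the list alone) (camera adjusted p = 7.98e-10, adjusted p = 0.373 with an estimated correlation). Calvin-Benson genes changed less upward or more downward, with CP12-2 (-1.22 ± 0.12) and CP12-1 (AT2G47400, -0.74 ± 0.095), and 0 of 20 measured were higher, 9 lower and 11 did not pass (2 and 15 adjusted over the list alone) (camera adjusted p = 6.47e-06, adjusted p = 0.373 with an estimated correlation). Of the starch list 4 of 34 measured were higher, 13 lower and 17 did not pass (4 and 17 adjusted over the list alone) (camera adjusted p = 1.41e-05, adjusted p = 0.373 with an estimated correlation). These took in BAM3 (-1.8 ± 0.082) and PWD (GWD3, AT5G26570, -2.37 ± 0.14). The plastid genes TRNS.2 (7.45 ± 1.22), TRNL.1 (6.75 ± 1.46), PSBZ (6.51 ± 0.64) and PSBE (ATCG00580, 5.82 ± 0.78) had the highest values, where plastid reads took 0.203 and 0.453% of the ilp1-1 libraries. AT5G43455 (-5.09 ± 0.66), the Rubisco assembly chaperone RBCX1 (AT4G04330, -4.69 ± 0.20), an unnamed transcript model (-4.33 ± 0.29) on chromosome 1 and the heat shock gene HSP17.6A (-4.27 ± 0.54) were lowest. ILP1 did not pass (-0.59 ± 0.25). Limma-voom ended the calls of TRNS.2 (adjusted p from 0.000115 to 0.129 over the alternatives) and PSBZ (1.85e-06 to 0.0858), and a pseudocount of 0.1 that of TRNL.1 (0.000934 to 0.0616). In all, 1804 genes passed, 815 higher and 989 lower. Total-read scaling gave 1048 and 792 (57% in place of 45.2% higher). The count was 1202 without Col-0 0 h replicate 2, 1179 without ilp1-1 4 h replicate 2 and 1060 on these 8 libraries alone.

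At 8 h the antenna genes had fallen less in ilp1-1, with LHCB1.1 (2.02 ± 0.078) and LHCB2.3 (2.79 ± 0.17). There 15 of 17 measured were higher, 1 lower and 1 did not pass (15 and 1 adjusted over the list alone) (camera adjusted p = 8.43e-16, adjusted p = 0.153 with an estimated correlation), with plastid reads at 0.0995 and 0.129% in the ilp1-1 libraries. Of the Calvin-Benson list 2 of 20 measured were higher, 12 lower and 6 did not pass (2 and 16 adjusted over the list alone) (camera adjusted p = 2.18e-08, adjusted p = 0.298 with an estimated correlation). Some of these were CP12-2 (-2.05 ± 0.12) and RBCS2B (-1.20 ± 0.078). Of the immunity list 8 of 25 measured were higher, 0 lower and 17 did not pass (11 and 0 adjusted over the list alone) (camera adjusted p = 0.000195, adjusted p = 0.663 with an estimated correlation). Among them were WRKY46 (1.8 ± 0.29) and PAD3 (2.56 ± 0.56). Of the photoprotection list 10 of 21 measured were higher, 2 lower and 9 did not pass (10 and 4 adjusted over the list alone) (camera adjusted p = 0.0358, adjusted p = 0.663 with an estimated correlation). They included ELIP2 (3.55 ± 0.29) and GPX7 (2.01 ± 0.18). The plastid genes TRNS.2 (5.22 ± 1.22), PSBZ (4.96 ± 0.64), TRNL.1 (4.63 ± 1.46) and PSBL (4.19 ± 0.83) had the highest values. AT5G43455 (-5.01 ± 0.66), the clock-related RVE2 (AT5G37260, -3.69 ± 0.31), AT2G41730 (-3.36 ± 0.37) and AT4G12735 (-3.27 ± 0.78) had the lowest, and ILP1 did not pass (-0.62 ± 0.25). The call of TRNL.1 (adjusted p from 0.000423 to 0.274 over the alternatives) ended without any 1 of its 8 libraries, with values from 4.23 without Col-0 0 h replicate 1 to 5.04 without Col-0 0 h replicate 2. It also ended with a pseudocount of 0.1, without a filter, without the trend and with the replicate block. Limma-voom and the pseudocount of 0.1 each ended the calls of TRNS.2 (0.0012 to 0.264), PSBL (0.00062 to 0.282) and AT4G12735 (0.00145 to 0.221), and limma-voom that of PSBZ (9.18e-05 to 0.207). In all, 2563 genes passed, 1253 higher and 1310 lower.

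At 16 h Calvin-Benson, photosystem and photoprotection genes parted the genotypes, and the antenna list was not called (3 of 17 higher, 6 lower, 8 not passing, 3 and 6 adjusted over the list alone, camera adjusted p = 0.648, adjusted p = 0.927 with an estimated correlation). For the Calvin-Benson list 0 of 20 measured were higher, 20 lower and 0 did not pass (0 and 20 adjusted over the list alone) (camera adjusted p = 7.87e-25, adjusted p = 0.0618 with an estimated correlation). Genes that passed included RBCS2B (-1.38 ± 0.078) and RCA (-1.52 ± 0.097). Photosystems gave 0 of 26 higher, 20 lower, 6 not passing, 0 and 23 adjusted over the list alone (camera adjusted p = 7.92e-14, adjusted p = 0.0618 with an estimated correlation). An example was PSBQ1 (-0.81 ± 0.07). Of photoprotection genes 1 of 21 measured were higher, 12 lower and 8 did not pass (1 and 15 adjusted over the list alone) (camera adjusted p = 9.51e-07, adjusted p = 0.0829 with an estimated correlation). Examples were PRXQ (-1.08 ± 0.086) and VTC2 (AT4G26850, -1.25 ± 0.12). ILP1 was lower by this measure (-1.08 ± 0.25, adjusted p = 0.00794). The highest values were the transfer RNA gene TRNS.3 (ATCG00370, 3.46 ± 0.77), CAD8 (AT4G37990, 2.95 ± 0.64), the nitrilase NIT2 (AT3G44300, 2.83 ± 0.90) and AT3G04165 (2.80 ± 0.63), and the lowest AT4G12735 (-5.71 ± 0.78), AT5G43455 (-5.01 ± 0.66), AT4G08555 (-4.61 ± 0.37) and AT2G42065 (-4.40 ± 0.24). The call of NIT2 (adjusted p from 0.00404 to 0.215 over the alternatives) ended without Col-0 0 h replicate 2 (1.68), Col-0 16 h replicate 1 (2.58), Col-0 16 h replicate 2 (3.07), ilp1-1 0 h replicate 1 (2.06), ilp1-1 16 h replicate 1 (2.92) or ilp1-1 16 h replicate 2 (2.74). It also ended with a pseudocount of 0.1, without a filter and without the trend. Limma-voom ended the calls of NIT2, AT3G04165 (7.61e-06 to 0.0735) and TRNS.3 (0.00154 to 0.082), and a fit on these 8 libraries alone those of ILP1 (0.00228 to 0.063), NIT2 and AT3G04165. In all, 2740 genes passed, 888 higher and 1852 lower. With total-read scaling these were 1887 and 1204 (61% in place of 32.4% higher), with the median of all genes at 0.14.

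At 30 h photosynthesis genes had changed further downward in ilp1-1. For photosystems 0 of 26 measured were higher, 26 lower and 0 did not pass (0 and 26 adjusted over the list alone), with PSAO (AT1G08380, -1.36 ± 0.10) and PSAN (-1.33 ± 0.10) (camera adjusted p = 1.57e-26, adjusted p = 0.0209 with an estimated correlation). Antenna genes gave 0 of 17 higher, 15 lower, 2 not passing, 0 and 15 adjusted over the list alone, with LHCB1.1 (-2.18 ± 0.078) (camera adjusted p = 6.59e-22, adjusted p = 0.0316 with an estimated correlation). The Calvin-Benson list gave 0 of 20 higher, 20 lower, 0 not passing, 0 and 20 adjusted over the list alone (camera adjusted p = 1.61e-21, adjusted p = 0.0316 with an estimated correlation), and chlorophyll synthesis 0 of 20 higher, 15 lower, 5 not passing, 0 and 17 adjusted over the list alone (camera adjusted p = 9.62e-13, adjusted p = 0.0209 with an estimated correlation). Immunity genes had risen more in ilp1-1, with EDS1 (1.3 ± 0.21) and WRKY54 (AT2G40750, 0.77 ± 0.16), and 14 of 25 measured were higher, 0 lower and 11 did not pass (16 and 0 adjusted over the list alone) (camera adjusted p = 8.22e-07, adjusted p = 0.318 with an estimated correlation). The highest values were TRNS.3 (4.33 ± 0.77), LTP4 (3.72 ± 0.95), AT1G06877 (3.39 ± 0.70) and the cation exchanger CAX3 (AT3G51860, 2.89 ± 0.41), and the lowest AT2G41730 (-4.92 ± 0.37), the glycosyltransferase UGT73C1 (AT2G36750, -4.79 ± 0.34), AT4G12735 (-4.73 ± 0.78) and HSP23.5 (-4.31 ± 0.42). ILP1 was at -0.98 ± 0.25 (adjusted p = 0.0133). The call of LTP4 (adjusted p from 0.00306 to 0.072 over the alternatives) ended without Col-0 0 h replicate 1 (3.38), Col-0 30 h replicate 2 (2.86) or ilp1-1 30 h replicate 2 (3.36). That of ILP1 (0.00722 to 0.0683) ended without Col-0 0 h replicate 1 (-0.76), Col-0 30 h replicate 2 (-0.90) or ilp1-1 0 h replicate 2 (-0.84), and on these 8 libraries alone. A pseudocount of 0.1 ended that of AT1G06877 (0.00141 to 0.0638). In all, 3252 genes passed, 1478 higher and 1774 lower. Total-read scaling gave 2413 and 1357 (64% in place of 45.5% higher, the median of all genes at 0.13).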

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

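The tests of plastid transcripts, of photosynthesis genes and of a wholesale exchange of labels were chosen only after the result was seen, while the splits and the test of single exchanges were not. Each value in the next 2 paragraphs is a difference between genotypes in the change from 0 h that passed its test, and the calls that ended under an alternative are named in the report.

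All values subtract the same 0 h genotype gap, so the 4 hours are not separate evidence. At 4 h, 1804 genes differed: TRNS.2 7.45, TRNL.1 6.75, PSBZ 6.51, PSBE 5.82, PAP2 2.98, FLS1 1.11, CP12-1 -0.74, CP12-2 -1.22, BAM3 -1.8, PWD -2.37, HSP17.7 -4.27, RBCX1 -4.69, AT5G43455 -5.09 and the unnamed transcript model on chromosome 1 -4.33. At 8 h, 2563 differed: TRNS.2 5.22, PSBZ 4.96, TRNL.1 4.63, PSBL 4.19, ELIP2 3.55, LHCB2.3 2.79, PAD3 2.56, LHCB1.1 2.02, GPX7 2.01, WRKY46 1.8, RBCS2B -1.20, CP12-2 -2.05, AT4G12735 -3.27, AT2G41730 -3.36, RVE2 -3.69 and AT5G43455 -5.01. At 16 h, 2740 differed: TRNS.3 3.46, CAD8 2.95, NIT2 2.83, AT3G04165 2.80, PSBQ1 -0.81, PRXQ -1.08, ILP1 -1.08, VTC2 -1.25, RBCS2B -1.38, RCA -1.52, AT2G42065 -4.40, AT4G08555 -4.61, AT5G43455 -5.01 and AT4G12735 -5.71. At 30 h, 3252 differed: TRNS.3 4.33, LTP4 3.72, AT1G06877 3.39, CAX3 2.89, EDS1 1.3, WRKY54 0.77, ILP1 -0.98, PSAN -1.33, PSAO -1.36, LHCB1.1 -2.18, HSP23.5 -4.31, AT4G12735 -4.73, UGT73C1 -4.79 and AT2G41730 -4.92.

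As list medians, the Calvin-Benson cycle stood at -0.27 at 4 h, -0.38 at 8 h, -0.85 at 16 h and -0.82 at 30 h. Photosystems stood at -0.56 and -0.87 at 16 and 30 h, and the antenna at 0.93 at 8 h and -1.31 at 30 h. Chlorophyll synthesis was at -0.62 at 30 h, starch at -0.33 and anthocyanin at 0.66 at 4 h. Photoprotection was at 0.21 and -0.56 at 8 and 16 h, and immunity at 0.63 and 0.91 at 8 and 30 h. All of these were called with camera's preset correlation, and with an estimated one only the photosystem, antenna, Calvin-Benson and chlorophyll lists at 30 h.

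Plastid-encoded transcripts were higher in the libraries labelled ilp1-1 at 4 h, 99 of 108 measured, with a median of 2.97. Less complete poly-A selection would raise mitochondrion-encoded transcripts as well, and their median of -0.50 argues against it. Size-factor scaling is argued against by the FPKM denominators, which stood at 0.889 to 0.91 times the recovered reads in Col-0 at 4 h and at 1.01 times in ilp1-1. They fix how far the scaling can move a gene, so the median of 3.02 with total-read scaling adds no separate evidence. A change of plastid RNA in ilp1-1 under high light, for example of its tails or its decay, may account for it, and so may a handling step shared by these libraries, and neither was tested.

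ILP1 was not lower in the libraries labelled ilp1-1. With genes chosen at the other 4 time points, 20 of 20 libraries lay nearer the genotype of their own label, which argues against exchanges of single libraries. Mean ILP1 levels were higher in the libraries labelled ilp1-1 at 5 of 5 time points. Whether all libraries carry the other genotype's label cannot be told apart from a mutant allele with an altered transcript, since FPKM over the whole gene also counts shortened messages. If the labels are right, a mutant allele that leaves ILP1 message in place might account for the values, which was not tested.

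Nuclear photosynthesis genes were lower in the libraries labelled ilp1-1, with a photosystem median of -0.71. Size-factor scaling as the whole cause is argued against by a median of -0.54 with total-read scaling. A lower share of mesophyll cannot be told apart from regulation: marker medians were 0.23 for guard cells, 0.11 for vascular tissue and -0.15 for meristem and flower, over 10, 9 and 6 markers measured, and their quartiles overlap. Of these 10, 9 and 5 were above 0 in every library, and without the other, FT, the third median was -0.06. The genotype itself stays among the open explanations.

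The number of genes that passed in the mean contrast was set against 100 splits of the libraries within time points, the real one included. Chance can be excluded, with 11037 genes for the real split against 7362 for the highest other (1 of 100 as large). The highest other split parts 4 of 5 time points by genotype, so its count points to the structure of the samples.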

How the results depend on the processing

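Total-read scaling, limma-voom on the recovered reads and the fit without the ilp1-1 libraries of 4 h and 8 h were chosen after seeing the data, while the other alternatives were planned. Of the 19 counts (genes passing in 18 contrasts and lists called in the mean contrast), all 19 stayed within 1.5 times their value with a pseudocount of 0.1, without a filter, with other size factors, with the replicate block, with total-read scaling and with limma-voom. So did all 18 gene counts without the trend, an option camera does not have, and all 13 that the fit without the ilp1-1 libraries of 4 h and 8 h could give. The mean contrast gave 11037 genes, 11015 with limma-voom, 8688 over the 3 remaining times in that last fit, and 10535 to 10820 with 1 library left out. It called 13 lists, 16 with total-read scaling.

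With the contrast's own libraries alone, 12 counts stayed within 1.5 times and 5 fell further, for causes not tested. The genotype difference called 1565 genes at 0 h (of 4292), 3878 at 4 h (of 5900), 3514 at 16 h (of 5343) and 3974 at 30 h (of 6573), and the difference of changes at 4 h 1060 (of 1804). The main fit pools all groups. Replicate chi-square per degree of freedom was 8.4 and 9.2 in ilp1-1 at 0 and 30 h, 3.7 to 4.8 elsewhere. Median log2 differences were 0.159 and 0.15 there, 0.126 to 0.151 elsewhere.

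Leaving out 1 library moved 5 counts beyond 1.5 times and kept 119, the lone sample left in a group being assumed to vary like the other groups. The genotype difference ranged from 2508 (without Col-0 0 h replicate 2) to 3282 at 0 h, 3767 (without ilp1-1 8 h replicate 2) to 4027 at 8 h (of 5700) and 3528 (without ilp1-1 16 h replicate 2) to 4069 at 16 h. The difference of changes at 4 h ranged from 1179 (without ilp1-1 4 h replicate 2) to 1612, with 1202 without Col-0 0 h replicate 2. ILP1, which did not pass there, took both signs: -0.24 to 0.27 in the genotype difference at 16 h, and in Col-0 -0.25 to 0.18 at 4 h, -0.18 to 0.25 at 8 h, -0.15 to 0.28 at 16 h and -0.34 to 0.0822 at 30 h. The cause was not tested.

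Of the 342 values of genes named in the report, each kept its direction and its side of the threshold with other size factors. That held for 341 with the replicate block, 341 with total-read scaling, 339 without the trend, 337 without a filter, 334 with a pseudocount of 0.1 and 329 with limma-voom. On the contrast's own libraries it held for 273, and 8 no longer passed. With 1 library left out it held in 2543 cases, in 33 a gene no longer passed, and the 8 changes of sign were those of ILP1 given here. No other alternative changed a direction.

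The replicate block gave 10993 genes in the mean contrast. Among the named genes it ended only the call of TRNL.1 in the difference of changes at 8 h (4.63, adjusted p = 0.0579, from 0.000423 to 0.274 over the alternatives). The paired reading of replicate numbers has no basis in the residuals: correlations ran from -0.148 to 0.126 over 45 pairs of groups, so these cross nothing.

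Depth and replicates set the limits. At 11.4 to 19.0 M reads, genes near 1 FPKM rest on few reads, and each group has 2 libraries. Time points are confounded with time of day.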

Other observations

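Ribosomal protein, histone and mitochondrial stress groups were formed only after the result was seen, so no group p-values are given. In Col-0 at 4 h, 182 of 197 cytosolic ribosomal protein genes rose and 1 fell (median 0.76), and in ilp1-1 177 rose and 2 fell. In the genotype mean, 13 of them were higher and 113 lower, which flips to 95 and 21 with total-read scaling. In that mean, 27 of 28 nuclear genes of plastid ribosomal proteins were lower and 1 higher (median -0.52). Histone genes were lower there too, 28 of 37 with 3 higher (median -0.31), or 19 and 4 with total-read scaling. All 8 genes of a mitochondrial stress list, among them AOX1A and HSP23.5, were higher there (median 2.18).

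The tests of 2 hypotheses were set before their results were seen. The mitochondrial genes may belong to a wider response at 0 h: of 12 other members of it, 11 were measured, 6 were higher, 0 lower, and the median was 0.90 (adjusted p = 0.0556 with an estimated correlation). A load on splicing might lower genes with many introns in ilp1-1, and the test came out the other way. FPKM may count unspliced transcripts too, so this does not decide on such a load. Genes with at least 10 introns had a median 0.26 above that of genes without introns, with -0.14 for 0, -0.031 for 1 to 3, 0.047 for 4 to 9 and 0.12 for 10 or more. Within 3 bins of mean expression the difference was 0.20 to 0.38.

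Over the 5 time points, 298 genes were higher and 632 lower in the libraries labelled ilp1-1 at each, against 0.769 and 1.6 if the times were independent, and 940 passed in both directions at different times.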
